A study of Homo sapiens with 24 samples.

How the data were processed

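The data are 1 table with 58395 Ensembl gene identifiers and 24 columns, 1 for each library. The signal in each column is a read count divided by 1 size factor per library, made by the authors before they deposited the table. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6, checked with FastQC 0.11, aligned to GRCh38 with STAR 2.7.4, counted with featureCounts of Subread 1.6.2 and normalised with DESeq2 1.32. Total RNA was taken with RNeasy and libraries were made with TruSeq RNA v2, per the sample records. The annotation release, the strand setting and any filter are not given in the sources used here.

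Whole reads were recovered from the table. In each column every value divided by the smallest step between values, 0.818 to 1.084, lay within 0.1 of a whole number, for 100% of the values. The recovered totals were 21.2 to 23.4 M reads in genes, and the share of reads in mitochondrially encoded genes was 3.65% to 6.24%. Gene names came from a name table that held 57754 of the identifiers, and coordinates from GENCODE release 29, which held 58275. A read was present in at least 1 library for 31862 genes. XIST and the Y chromosome genes were left out of the named genes.

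Differences were tested with limma on log2 of the value plus 1, with an intensity trend, 8 group means and all 24 libraries (16 residual degrees of freedom). Genes with a value of at least 10 in at least 3 libraries were tested, which left 17314. In each of 12 comparisons p was adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. These covered suspension in each line and glucose, 5 mM glucose in each line and attachment state, the attached lines at 25 mM, and 3 differences of responses. A number of replicate was not used to pair libraries. Lists of genes, 35 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

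Genes were named by a fixed rule. For suspension these are CROT and CRAT and then the 10 highest and 10 lowest genes in each line, ranked by the smaller absolute log2 fold change of the 2 glucose concentrations. They had to be called with the same sign at both, have a mean of at least 100 in the higher group, and have all 3 libraries of one group on one side of the other. The same rule was used for glucose over the 2 attachment states, and where fewer than 10 genes in a direction were called in both states, counted before the level and separation rules, genes called in either state were taken. For the rise in 501mel this limit was met and 7 genes passed the further rules, so the largest rises in attached cells alone were not named by it. Between the lines the 10 highest and 10 lowest were taken, and for each difference of responses the 5 largest each way with a mean of at least 100 in some group. From each list up to 4 members with the smallest p were named.

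The code was tested on simulated data with the measured means and library sizes, 200 changed genes, 1 list shifted by 0.4 on the log2 scale and 30 lists left unshifted. The first run, with a dispersion of 0.01, stopped because limma recovered 88% of genes changed 2-fold, under a requirement of 95% that had been set beforehand. The requirement was then replaced by others on direction, on recovery of at least 90% at 4-fold and on the shifted list, and a second run with dispersions estimated from these reads was added, with a median of 0.00235. Both runs were kept. limma recovered 16%, 62%, 88% and 100% of genes changed 1.25, 1.5, 2 and 4-fold in the first run and 54%, 74%, 94% and 100% in the second. False calls were above the nominal level with limma, at 26 of 163 calls (16%) in the first and 48 of 227 (21.1%) in the second, and 24 and 41 of these were in genes with a mean under 20. With edgeR they were 6 of 154 (3.9%) and 17 of 204 (8.33%), and with DESeq2 10 of 162 (6.17%) and 9 of 192 (4.69%). In both runs the shifted list was called, 0 of 30 unshifted lists were called and no recovered gene had the wrong direction. The simulated genes were drawn independently of each other and few of them were changed. The 0 of 30 therefore does not show how often camera calls lists of correlated genes.

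Other settings were pseudocounts of 0.5 and 10, no filter, a filter on the mean, quantile normalization, equal totals, a fit of only the libraries compared, array weights, a robust fit, edgeR, DESeq2, a block for the replicate number, stricter thresholds and leaving out each library. Another 4 were chosen after seeing the data. They are a mean of at least 20 in a compared group, that filter with only the libraries compared, and the lists under quantile normalization and under equal totals. The filter was added after the simulation, where most false calls of limma lay in genes with a mean under 20. The fit of only the libraries compared also met genes without any variance, 216 in adherent 501mel at 5 mM and 50 in suspended WM266-4. How far these genes account for its counts was not tested. DESeq2 gave no adjusted p for 3693 genes in suspended 501mel and 6042 in each state of WM266-4 at 5 mM. Splice forms, variants and reads outside genes cannot be studied from this table and were left out.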

Results

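Gene expression was measured by RNA sequencing in 2 human melanoma cell lines. 501mel is labelled as differentiated and proliferative, and WM266-4 as undifferentiated and invasive. Each line was grown attached to the dish or in suspension, with 25 or 5 mM glucose in the medium, which gave 8 groups of 3 libraries and 24 libraries in all. Each library held between 21.2 and 23.4 M reads in genes, and between 21292 and 23993 genes had at least 1 read. Levels are normalised read counts with their SD over n = 3 libraries, and log2 fold changes carry the SE of 1 limma fit to all 24 libraries. That fit shares 1 spread per gene over all groups, so its SE may be too small for some groups and too large for others. Over genes with a mean of at least 100, the median replicate SD (log2, 25 and 5 mM) was 0.0457 and 0.0445 in adherent WM266-4. In suspended WM266-4 it was 0.0651 and 0.0767, in adherent 501mel 0.0593 and 0.0678, and in suspended 501mel 0.077 and 0.0659. The labels do not say whether the replicates of a group are separate cultures, so the p-values measure only the spread between these samples. The comparisons, the gene lists, the rule for the genes named and most of the other settings tried were fixed before the data were examined. The first principal component held 81.9% of the variance and parted the lines, and the second, with 9.3%, parted attached from suspended cells.

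**Figure D1:**
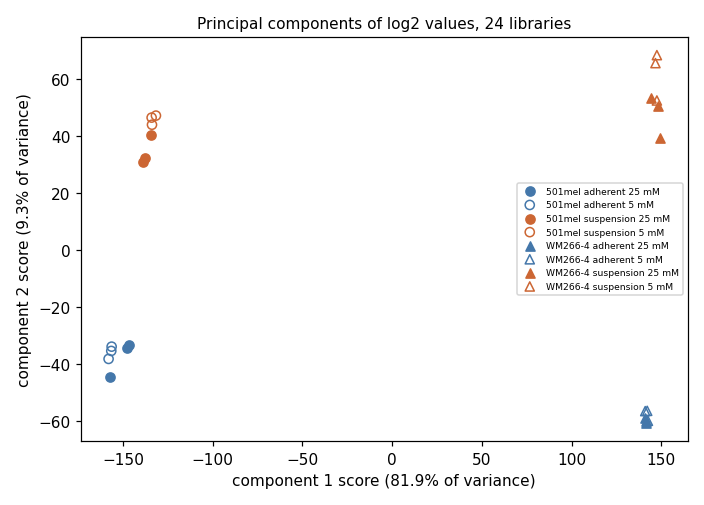
Scores of the 24 libraries on the first and second principal components of the log2 values (axes in arbitrary units, with 81.9% and 9.3% of the variance); circles are 501mel, triangles WM266-4, blue adherent, orange suspension, filled 25 mM and open 5 mM glucose. The lines lie apart on the first axis and the attachment states on the second.

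The series title names CROT and CRAT, so these genes were examined first. CROT (ENSG00000005469, GRCh38 chromosome 7, 87345681 to 87399795, + strand) encodes the peroxisomal carnitine octanoyltransferase, and CRAT (ENSG00000095321, chromosome 9, 129094810 to 129111189, − strand) encodes carnitine acetyltransferase. In 501mel at 25 mM glucose, CROT rose in suspension from 200.2 ± 4.23 to 393.9 ± 20.2 normalised counts (SD, n = 3), and CRAT rose from 172.5 ± 9.89 to 444.7 ± 8.02. At 5 mM the same line went from 169.6 ± 23.1 to 388.6 ± 9.51 for CROT and from 132.4 ± 14.7 to 459.4 ± 7.78 for CRAT. These are rises of 1.96-fold and 2.3-fold for CROT (adjusted p = 1.8e-11 and 2.6e-13) and of 2.57-fold and 3.46-fold for CRAT (adjusted p = 2.6e-15 and 1.1e-17), with all 3 suspension libraries above all 3 adherent libraries in each case. WM266-4 started higher, with 638.9 ± 20.9 counts of CROT and 1114 ± 40.7 of CRAT in attached cells at 25 mM. There CROT rose in suspension by 0.37 ± 0.07 on the log2 scale (SE; 1.29-fold, adjusted p = 8.6e-05) and at 5 mM by 0.23 ± 0.07 (1.18-fold, adjusted p = 0.0063), again with 3 of 3 suspension libraries above the adherent ones. CRAT in WM266-4 had a log2 change of 0.12 ± 0.06 at 25 mM (adjusted p = 0.088) and 0.04 ± 0.06 at 5 mM (adjusted p = 0.59). The suspension response was smaller in WM266-4 than in 501mel for both genes, with a difference of −0.79 ± 0.07 for CROT (adjusted p = 6.5e-10) and −1.5 ± 0.06 for CRAT (adjusted p = 2e-16). Under quantile normalization, scaling to equal totals or a fit of only the compared libraries, CRAT in WM266-4 at 25 mM did pass the threshold, and over all alternatives its adjusted p lay between 0.0039 and 0.22.

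**Figure D2:**
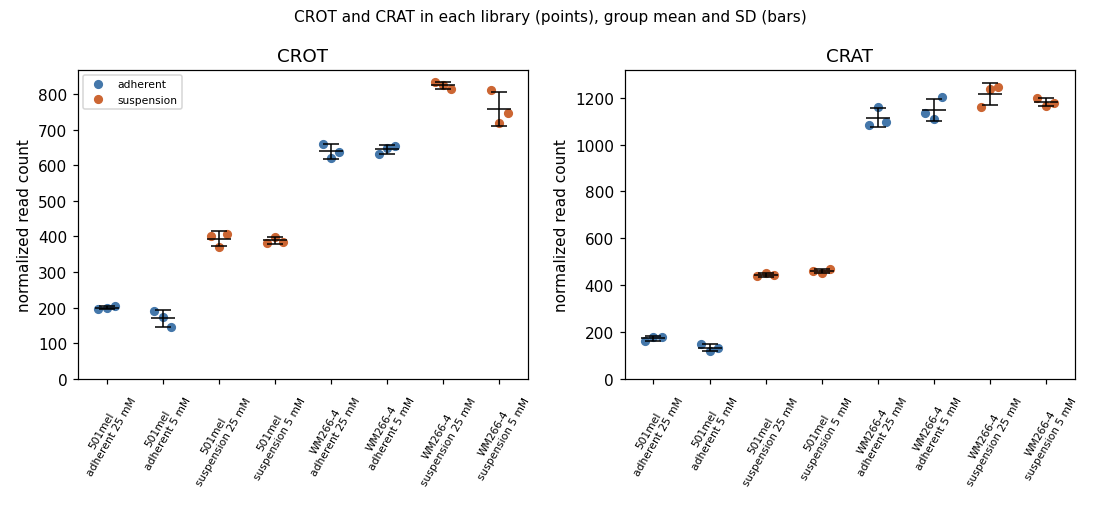
Normalised read counts of CROT and CRAT in each library (points), with the mean of each group of 3 (horizontal marks) and its SD (error bars). In 501mel both genes stand at 370.8 counts or more in every suspension library and at 204.4 or less in every adherent library.

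In adherent 501mel, 5 mM glucose lowered CROT by a log2 change of −0.25 ± 0.07 (1.19-fold, adjusted p = 0.0099) and CRAT by −0.38 ± 0.06 (1.3-fold, adjusted p = 4.6e-05), with 3 of 3 libraries below those at 25 mM. The CROT call ended with only the compared libraries (adjusted p = 0.16, with a range of 0.00076 to 0.16 over its alternatives) and without replicate 3 at 5 mM. In suspension their changes were −0.02 (adjusted p = 0.96) and 0.05 (adjusted p = 0.84). The difference between the states passed the test for CRAT, at 0.43 ± 0.09 (adjusted p = 0.0013), and not for CROT, at 0.23 ± 0.1 (adjusted p = 0.13), though it did for CROT with array weights and without replicate 1 of adherent cells at 5 mM. In WM266-4 the glucose changes of both genes lay between −0.12 and 0.04, with adjusted p of at least 0.36.

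Which genes differed between suspended and attached 501mel cells was asked next. TXNIP (ENSG00000265972, GRCh38 chromosome 1, 145992435 to 145996600), which encodes a thioredoxin-binding protein that restrains glucose uptake, rose from 195.9 ± 17.2 to 3246 ± 67.6 counts at 25 mM (SD, n = 3) and from 131.8 ± 12.9 to 2477 ± 93 at 5 mM. Its relative ARRDC4 (ENSG00000140450) rose 18.2-fold at 25 mM and 13.9-fold at 5 mM. The secreted chaperone gene CLU (ENSG00000120885) rose 38.6-fold and 68-fold, the membrane-repair gene MYOF (ENSG00000138119) 34.9-fold at both concentrations, the cytokine gene IL24 26.7-fold and 26.3-fold, and RNASE1 25.7-fold and 29.2-fold. DLK1 stood at 1.243 ± 1.08 counts in attached and 171.3 ± 12.8 in suspended cells at 25 mM, and SNTG2, SPRR2D and SDSL rose by log2 changes of between 3.8 and 6.04. The growth-factor-induced transcription factor genes EGR1 (ENSG00000120738) and EGR3 fell: EGR1 went from 3861 ± 206 to 331 ± 38.3 counts at 25 mM and from 8784 ± 402 to 388 ± 51.9 at 5 mM. The cytokine genes LIF and CXCL8 (ENSG00000169429) were 14.2-fold and 12.3-fold lower at 25 mM, and DHCR7 (ENSG00000172893, chromosome 11, 71428193 to 71452868), which encodes the last enzyme of one branch of cholesterol synthesis, was 9.22-fold lower. PERM1, PLEKHN1, FAM167B, CALCR and LRAT had log2 changes of between −2.71 and −4.13. PERM1 (chromosome 1, 975204 to 982093) and PLEKHN1 (966497 to 975865) overlap, and whether they share reads was not tested. As the rule for naming genes required, the 3 suspension libraries lay on one side of the 3 adherent ones at both concentrations for each gene named here. The largest adjusted p was 1.1e-06. The limma fit called 10151 of 17314 genes at 25 mM, 5271 higher and 4880 lower, and 10951 at 5 mM, 6055 higher and 4896 lower, of which 2500 and 3069 changed at least 2-fold. Of these calls 1094 and 1326 lay below a mean of 20 counts, where most false calls of limma fell on simulated data. Scaling to equal totals moved the median of all genes by 0.123 and 0.139 on the log2 scale and the share of called genes that were higher from 51.9% to 64.4% and from 55.3% to 66.9%, and quantile normalization moved the median at 5 mM by −0.111.

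Lists of lipid genes were tested in suspended 501mel. Counts of list members are those called over all genes, with the count adjusted over the list alone where it differs. The adjusted p beside such a count is that of camera for the whole list. Of 24 measured genes of cholesterol synthesis and the SREBP2 targets, 23 fell and 0 rose at each glucose concentration. LSS was 4.96-fold and ACAT2 5.67-fold lower at 25 mM, and the list's median log2 change was −1.68 at 25 mM and −1.63 at 5 mM. The camera test compares a list with all other genes. It gave adjusted p = 1.2e-20 and 5.5e-19, or 0.025 and 0.036 with an estimated correlation. Over all 12 comparisons camera called 164 of the list results, and 14 of these hold with an estimated correlation. They are cholesterol synthesis in the 4 suspension comparisons, 3 lists each in adherent 501mel and adherent WM266-4 at 5 mM glucose, and 4 between the lines. The fry test asks whether the genes of a list move on balance one way, and its mixed form whether they move in either direction, and neither compares them with other genes; fry called 244. Of 13 fatty acid synthesis genes 9 fell and 1 rose at each concentration, among them FASN, fatty acid synthase, at −2.1 ± 0.09 (SE) and SCD, a fatty acid desaturase, at −1.47 ± 0.06 at 25 mM. That list had adjusted p = 7.8e-06 and 3.2e-05, and 0.17 and 0.21 with an estimated correlation. Of 18 genes of peroxisomal fatty acid oxidation and the acyl-carnitine shuttle, 9 rose and 1 fell at 25 mM (median 0.23) and 10 rose and 1 fell at 5 mM (median 0.3). EHHADH, a bifunctional enzyme of peroxisomal beta-oxidation, rose 3.86-fold and 3.13-fold, and PHYH, which starts the breakdown of phytanic acid, 1.86-fold and 1.92-fold. The list's adjusted p = 0.011 and 0.025 became adjusted p = 0.17 and 0.24 with an estimated correlation. CROT and CRAT, which the series title names, are members of this list and among its risers here. In no comparison was the list tested without them. Of 15 peroxisome biogenesis genes 9 rose and 1 fell at 25 mM (adjusted p = 0.025, and 0.17 with an estimated correlation). At 5 mM 7 rose and 1 fell (adjusted p = 0.24). Of 20 genes of mitochondrial fatty acid oxidation 13 rose and 5 fell at 25 mM, with CPT1A, the carnitine palmitoyltransferase at the entry of the pathway, up 3.15-fold and ACSL1 down 1.72-fold (adjusted p = 0.033, and 0.32 with an estimated correlation). At 5 mM 11 rose and 5 fell, 6 over the list alone (adjusted p = 0.2).

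Lists of sugar and energy genes were also tested. Of 22 genes of glycolysis and glucose transport 14 fell and 4 rose at each concentration, with the kinase genes PFKFB3 at −1.29 ± 0.04 and HK2 at −1.07 ± 0.05 at 25 mM and the glucose transporter gene SLC2A1 opposite, at 1.5 ± 0.06 (SE). Its adjusted p = 0.0069 and 0.0099 became adjusted p = 0.5 and 0.53 with an estimated correlation. Of 18 genes of the tricarboxylic acid cycle 11 fell and 3 rose at 25 mM and 12 fell and 2 rose at 5 mM, led by PC, pyruvate carboxylase, 3.09-fold and 3.12-fold lower (adjusted p = 0.033 and 0.011, and 0.5 and 0.43 with an estimated correlation). The 7 MondoA and ChREBP targets, glucose-responsive genes that include TXNIP and ARRDC4, had 4 higher and 1 lower at 25 mM and 5 higher and 1 lower at 5 mM (6 higher when adjusted over the list alone), with adjusted p = 0.036 and 0.034, and 0.17 and 0.2 with an estimated correlation. Of 13 mitochondrially encoded mRNAs 9 fell at 25 mM, 10 when adjusted over the list alone, and 0 rose (median −0.35, adjusted p = 0.011, and 0.65 with an estimated correlation). The mean share of reads in mitochondrially encoded genes at 25 mM was 5.37% (SD 0.335, n = 3) in attached and 4.29% (SD 0.672) in suspended cells. Suspension replicate 3, at 4.99%, lay close to the lowest attached library, at 5.04%. At 5 mM 7 fell (adjusted p = 0.09). Quantile normalization ended the calls of glycolysis, the tricarboxylic acid cycle, the mitochondrial mRNAs and, at 25 mM, MondoA targets, and scaling to equal totals ended those of the tricarboxylic acid cycle and of the MondoA targets.

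Cell cycle and signalling lists went different ways in 501mel. Of 21 G2 and M phase genes 17 rose and 0 fell at each concentration, with UBE2C up 2.1-fold and CDC20 1.78-fold at 25 mM (median 0.35, adjusted p = 2e-04) and a median of 0.46 at 5 mM (adjusted p = 4.5e-05). Adjusted p was 0.5 and 0.52 with an estimated correlation. Of 20 S phase genes 16 fell and 0 rose at 25 mM, among them CDC6 by 1.74-fold and E2F1 by 1.92-fold (adjusted p = 4.9e-05, and 0.28 with an estimated correlation), whereas at 5 mM 5 rose and 5 fell (adjusted p = 0.94). The median there was −0.02, the mean 0.08 and the test pointed up, and the median turned to 0.09 under quantile normalization and 0.12 under equal totals. Of 16 immediate early genes, which growth signals switch on within minutes, 12 fell and 1 rose at 25 mM (2 rose over the list alone) and 14 fell and 0 rose at 5 mM, with adjusted p = 0.00016 and 7.6e-08, and 0.22 and 0.17 with an estimated correlation. DUSP6 was 2.57-fold and IER3 2.95-fold lower at 25 mM. Of 15 NF-kappaB and cytokine genes 11 fell and 1 rose at 25 mM, 2 over the list alone, and 10 fell and 2 rose at 5 mM, with NFKBIA, an inhibitor of NF-kappaB and itself its target, 2.7-fold lower at 25 mM (adjusted p = 0.00075 and 0.0062, and 0.17 and 0.2 with an estimated correlation). Of 18 genes of melanocyte differentiation and MITF targets 12 fell at each concentration (13 at 5 mM over the list alone), with 3 and 2 higher, and the pigment enzyme gene DCT was 5.12-fold and 7.45-fold lower (adjusted p = 0.00056 and 3.2e-05, and 0.17 and 0.17 with an estimated correlation). At 25 mM 11 of 14 NRF2 targets rose and 3 fell, led by the ferritin gene FTL at 1.29 ± 0.03 and the quinone reductase gene NQO1 at 1.17 ± 0.04 (SE; adjusted p = 0.0071, and 0.45 with an estimated correlation). In addition 20 of 23 cytosolic ribosomal protein genes rose and 2 fell (median 0.17, adjusted p = 0.002, and 0.5 with an estimated correlation). At 25 mM 9 of 15 p53 targets rose and 3 fell, with BMF, a BH3-only gene linked to anoikis, 4.27-fold higher (adjusted p = 0.049, and 0.17 with an estimated correlation). In addition 9 of 17 unfolded protein response genes fell and 3 rose (adjusted p = 0.036, and 0.5 with an estimated correlation). At 5 mM 12 of 21 ATF4 genes fell and 5 rose, with CHAC1 3.46-fold lower and PHGDH 1.53-fold higher (adjusted p = 0.047, and 0.61 with an estimated correlation). In addition 13 of 21 SRF targets fell and 4 rose (adjusted p = 0.026, and 0.3 with an estimated correlation). Quantile normalization and equal totals each ended these last 4 calls. In attached cells most ATF4 genes and SRF targets were called higher at 5 mM than at 25 mM, as given below. Their fall in suspension at 5 mM is therefore measured against a raised attached level. No ATF4 gene was called for glucose in suspended cells.

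**Figure D3:**
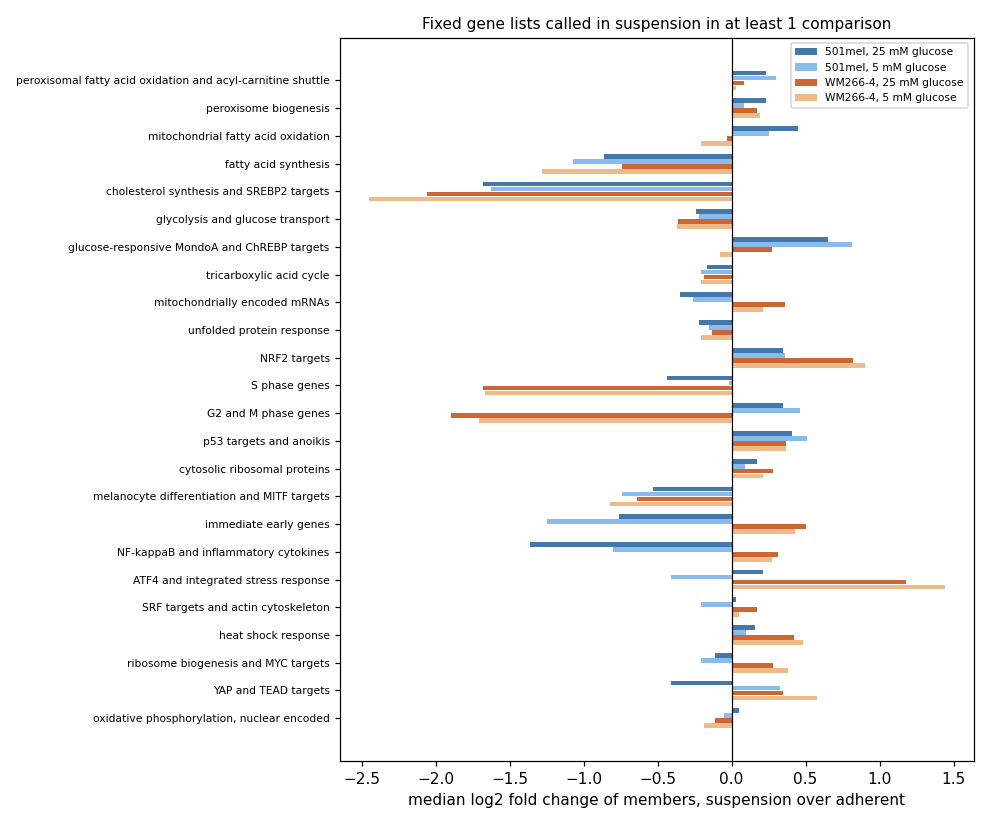
Median log2 fold change of the measured members of each fixed gene list, suspension against adherent (horizontal axis), in the 4 combinations of line and glucose, for lists called in at least 1 of them. Cholesterol synthesis lies below 0 in all 4, at −1.68, −1.63, −2.06 and −2.45, while G2 and M phase genes lie above 0 in 501mel and below it in WM266-4 under the deposited scaling and under both other scalings tried.

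The same comparison was made in WM266-4. TRPM1 (ENSG00000134160, GRCh38 chromosome 15, 31001061 to 31161273), a channel gene regulated by MITF in melanocytes, fell 26.6-fold in suspension at 25 mM and 47.6-fold at 5 mM, and sterol genes followed. DHCR7 was 19.2-fold and 26.8-fold lower, ACAT2 14.3-fold and 21.2-fold, HMGCS1 10.9-fold and 12.1-fold, and INSIG1 (ENSG00000186480), an inhibitor of SREBP processing, 10.5-fold and 11.1-fold. The desaturase gene SCD was 10.4-fold and 12.4-fold lower, and SCML4, GALNT3, ACSBG1 and FAM167B had log2 changes of between −3.24 and −4.48. SERPINB2 (ENSG00000197632), a plasminogen activator inhibitor gene, rose 89.4-fold and 165-fold from 3.6 and 4.463 counts, IL36B 65.1-fold and 51.9-fold, SULT1C2 54.9-fold and 79.6-fold, and CHGA, a secretory granule protein gene, 42.8-fold and 42.6-fold. Folds are of values plus 1, which lowers them where attached levels are near 0, as for SULT1C2 at 2.613 and 4.127 counts. MAGEB2, DCDC2C, CALB2 and IGFN1 rose by log2 changes of between 5.34 and 6.41, and INHBA, with 5 and 8 reads over the attached libraries, by 5.87 and 6.65. SPANXB1 reached 148.9 ± 39 counts at 25 mM from attached libraries listed at 0. As the naming rule required, the 3 suspension libraries lay on one side of the 3 adherent ones for each of these genes at both concentrations. The largest adjusted p was 3.9e-08. The limma fit called 10634 genes at 25 mM, 5634 higher and 5000 lower, and 11056 at 5 mM, 5755 higher and 5301 lower, and 3046 and 3401 of them changed at least 2-fold. Of these calls 1087 and 1033 lay below a mean of 20 counts, and whether reads of SPANXB1 and MAGEB2 are shared with close relatives was not tested.

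The lists of sterol and cell cycle genes had the smallest adjusted p in suspended WM266-4. All but 1 of the 24 cholesterol synthesis genes fell at 25 mM and all 24 at 5 mM, with medians of −2.06 and −2.45 (adjusted p = 5.9e-21 and 2.6e-21, and 0.024 and 0.022 with an estimated correlation). Of 13 fatty acid synthesis genes 11 fell at each concentration, with FASN at −2.61 ± 0.09 and FADS2 at −2.74 ± 0.05 at 25 mM (SE; adjusted p = 4.1e-08 and 4.3e-07, and 0.072 and 0.11 with an estimated correlation). All 21 G2 and M phase genes fell at both concentrations, CDK1 by 3.74-fold and AURKB by 5.94-fold at 25 mM, with medians of −1.9 and −1.71 (adjusted p = 8.1e-21 and 2.6e-18, and 0.072 and 0.1 with an estimated correlation). Of 20 S phase genes 19 fell at each, with MCM7, a subunit of the replicative helicase, 3.76-fold lower at 25 mM (adjusted p = 2.1e-15 and 2.9e-13, and 0.072 and 0.083 with an estimated correlation). Of 18 MITF targets 14 fell and 2 rose at 25 mM and 16 fell and 2 rose at 5 mM (adjusted p = 2.6e-06 and 6.6e-07, and 0.072 and 0.083 with an estimated correlation). Of 21 ATF4 and integrated stress response genes 17 rose at each concentration, with 2 and 1 lower. ATF4 itself was 3.2-fold, NUPR1 5.27-fold and PSAT1, an enzyme of serine synthesis, 2.73-fold higher at 25 mM (medians 1.18 and 1.44, adjusted p = 1.3e-06 and 1.5e-07, and 0.28 and 0.2 with an estimated correlation). Of 14 NRF2 targets 12 rose and 2 fell at each, with PRDX1 at 2.12 ± 0.04 and TXNRD1 at 2.18 ± 0.09 (adjusted p = 4.7e-06 and 4.2e-06, and 0.18 and 0.17 with an estimated correlation).

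Other lists called in WM266-4 covered translation, contact and energy genes. Of 22 YAP and TEAD targets 10 rose and 2 fell at 25 mM and 14 rose and 1 fell at 5 mM, with CCN1 (ENSG00000142871), a matricellular protein gene, 25.7-fold and 34.9-fold higher (adjusted p = 0.025 and 0.0023, and 0.35 and 0.2 with an estimated correlation). Of 16 immediate early genes 12 and 11 rose and 2 fell, led by DUSP6 and ATF3, up 2.01-fold and 3.84-fold at 25 mM (adjusted p = 0.014 and 0.0096, and 0.38 and 0.38 with an estimated correlation). Ribosome biogenesis genes and MYC targets had 14 and 13 of 18 members higher and 3 and 4 lower (4 lower at 25 mM over the list alone), with ODC1 up 5.21-fold at 25 mM (adjusted p = 0.0012 and 0.0042, and 0.28 and 0.29 with an estimated correlation). In addition 20 and 16 of 23 ribosomal protein genes rose (medians 0.28 and 0.21, adjusted p = 1.3e-06 and 0.00074, and 0.29 and 0.38 with an estimated correlation). Of 12 heat shock genes 8 rose at each, BAG3 by 2.27-fold at 25 mM (adjusted p = 0.044 and 0.043, and 0.38 at each concentration with an estimated correlation). Of 22 glycolysis genes 16 and 14 fell (17 at 25 mM over the list alone) and 2 and 5 rose, with PFKL 1.8-fold lower at 25 mM (adjusted p = 0.00011 and 0.0044, and 0.35 and 0.38 with an estimated correlation). In addition 12 and 13 of 18 tricarboxylic acid cycle genes fell, PC by 2.91-fold (adjusted p = 0.0015 and 0.00056, and 0.28 and 0.2 with an estimated correlation). At 5 mM 22 of 29 nuclear genes of oxidative phosphorylation fell and 1 rose, with UQCRC1 1.98-fold lower (median −0.19, adjusted p = 0.00024, and 0.25 with an estimated correlation). In addition 10 of 20 mitochondrial fatty acid oxidation genes fell, 11 over the list alone, and 4 rose, with ACADM 1.95-fold lower and CPT1A 2.15-fold higher (adjusted p = 0.023, and 0.25 with an estimated correlation). Of the 13 mitochondrially encoded mRNAs 9 rose at 25 mM (median 0.36, adjusted p = 0.031, and 0.52 with an estimated correlation). The mean share of mitochondrial reads at 25 mM was 4.73% (SD 0.405, n = 3) in attached and 5.85% (SD 0.578) in suspended cells. Quantile normalization ended the calls of the mitochondrial mRNAs and, at 5 mM, of mitochondrial fatty acid oxidation. The peroxisomal fatty acid oxidation list had 7 higher and 4 lower at 25 mM (adjusted p = 0.58) and 5 higher and 6 lower at 5 mM, with a median of 0.03, a mean of −0.08 and a test that pointed down (adjusted p = 0.97) and turned up under quantile normalization.

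Whether suspension acted differently in the lines was tested as the difference of the responses, averaged over glucose. The G2 and M phase genes parted most, with all 21 members lower in the WM266-4 response, a median difference of −2.37, and CDK1 at −2.5 ± 0.04 (SE; adjusted p = 1.7e-20, and 0.052 with an estimated correlation). All 20 S phase genes went the same way, by a median of −1.55 (adjusted p = 1.8e-13, and 0.052 with an estimated correlation). Of 16 immediate early genes 15 had a higher response in WM266-4, with EGR1 at 4.49 ± 0.09 (adjusted p = 3.4e-09, and 0.052 with an estimated correlation). So had 13 of 15 NF-kappaB genes (14 over the list alone) with CXCL8 at 5.49 ± 0.14 (adjusted p = 3e-05, and 0.052 with an estimated correlation) and 20 of 21 ATF4 genes with CHAC1 at 3.73 ± 0.12 (adjusted p = 7.7e-09, and 0.15 with an estimated correlation). Peroxisomal fatty acid oxidation was lower in 13 of 18 members and higher in 2, with EHHADH at −1.07 ± 0.06 and CRAT at −1.5 ± 0.06 (adjusted p = 0.012, and 0.15 with an estimated correlation). Mitochondrial fatty acid oxidation was lower in 16 of 20 (17 over the list alone) and higher in 2, with SLC25A20, the carnitine carrier, at −1.42 ± 0.09 (adjusted p = 0.00011, and 0.052 with an estimated correlation). The fall of cholesterol genes was deeper in WM266-4 for 19 of 24 members and shallower for 3 (median −0.68, adjusted p = 4.8e-06, and 0.19 with an estimated correlation). The cytosolic ribosomal proteins, 10 of 23 higher (9 over the list alone) with a median of 0.07 (adjusted p = 0.026, and 0.58 with an estimated correlation), turned to −0.05 under quantile normalization and −0.01 under equal totals. In all, limma called 10837 differences, 5235 higher and 5602 lower, 3220 of them at least 2-fold.

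The responses of the lines also shared genes. At 25 mM 5691 genes were called the same way in both lines, where 3124 would be expected from independent calls, and 1521 opposite ways, where 3110 would be expected. At 5 mM 5496 went the same way, with 3512 expected, and 2247 opposite ways, with 3481 expected. Across 17314 genes, which are not independent replicates, the log2 fold changes of the lines correlated at r = 0.43 (rho = 0.43) at 25 mM and r = 0.42 (rho = 0.37) at 5 mM. Within 501mel the responses at 25 and 5 mM shared 8213 genes, with 221 opposite (r = 0.83, rho = 0.79), and within WM266-4 they shared 9180, with 25 opposite (r = 0.93, rho = 0.9).

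What 5 mM glucose changed in 501mel was compared within each attachment state. In attached cells stress genes rose and S phase genes fell. Of 21 ATF4 and integrated stress response genes 18 rose, 19 when adjusted over the list alone, and 0 fell. CHAC1 (ENSG00000128965), a glutathione-degrading enzyme gene, went from 475.6 ± 19.9 to 1442 ± 146 counts (SD, n = 3), and SESN2, an inhibitor of mTORC1, rose 2.98-fold (median 0.5, adjusted p = 2.4e-17, and 0.046 with an estimated correlation). Of 20 S phase genes 18 fell, 19 over the list alone, and 0 rose, with the cyclin gene CCNE1 (ENSG00000105173) 2.38-fold and CDC6 1.81-fold lower (median −0.41, adjusted p = 1.9e-15, and 0.046 with an estimated correlation). Of 21 SRF targets and actin genes 12 rose and 1 fell, 14 and 1 over the list alone, with ZYX up 1.65-fold (adjusted p = 2.1e-07, and 0.034 with an estimated correlation). Of 16 immediate early genes 14 rose and 1 fell, with EGR1 2.28-fold and ATF3 2.88-fold higher (adjusted p = 5.8e-08, and 0.12 with an estimated correlation). In addition 19 of 23 ribosomal protein genes rose (median 0.15, adjusted p = 3.2e-09, and 0.22 with an estimated correlation). Of 21 G2 and M phase genes 13 fell, 16 over the list alone, with KIF11 at −0.37 ± 0.06 (adjusted p = 4.1e-05, and 0.48 with an estimated correlation). Of 17 unfolded protein response genes 11 fell, 12 over the list alone, and 3 rose, with SDF2L1 at −0.62 ± 0.06 and HERPUD1 at 1 ± 0.1 (adjusted p = 0.0068, and 0.48 with an estimated correlation). Of 22 extracellular matrix genes 9 fell, 10 over the list alone, and 0 rose, with COL5A1 1.5-fold lower (adjusted p = 0.0068, and 0.22 with an estimated correlation). CCNE2, CDC25A, FAM111B, LRFN1, KCTD12, SLC35E4, ZFTA and AMOTL2 fell by log2 changes of −0.99 to −1.26 and the mitochondrial tRNA gene MT-TF by −1.37, while in suspension their changes lay between −0.47 and 0.64 with adjusted p of at least 0.1. The glucose-responsive MondoA list had 2 higher and 2 lower (median −0.2, adjusted p = 0.74).

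In suspended 501mel fewer genes passed. CXCL1, a chemokine gene, rose 2.68-fold (adjusted p = 0.00082) and SERPINE2, a serine protease inhibitor gene, 1.27-fold (adjusted p = 0.0028), with 3 of 3 libraries at 5 mM above those at 25 mM for SERPINE2, which also rose in attached cells by 0.32 ± 0.05. Its suspension call ended under quantile normalization and with only these 6 libraries and all genes in the fit. LPXN, UGT2B7, UPP1, CNN2, HDAC5 and RPL3 were called higher in both states too, by log2 changes of between 0.13 and 0.6. Their suspension calls ended with only these 6 libraries in the fit, and all 6 ended without suspension 25 mM replicate 1 or without 5 mM replicate 1, 5 of them without replicate 2 of either group, and 4 without 5 mM replicate 3. The ribosomal protein list had 1 of 23 members called, 18 adjusted over the list alone, and a median of 0.09 (adjusted p = 1.3e-11, and 0.17 with an estimated correlation). Of 15 NF-kappaB genes 2 rose, and 4 rose and 1 fell over the list alone (adjusted p = 0.00049, and 0.13 with an estimated correlation), while the ATF4 and S phase lists had 0 members called either way (adjusted p = 0.69 and 0.93). The limma fit called 5325 genes in attached cells, 2439 higher and 2886 lower, 457 of them at least 2-fold, and 77 in suspension, 52 higher and 25 lower, 19 at least 2-fold. The second count moved with the setting, for causes that were not tested. It was 26 with only these 6 libraries and a mean of at least 20 (chosen after seeing the data). With edgeR it was 109, with DESeq2 189 and with array weights 1656. Without 1 library of suspension it was 15 (25 mM replicate 1), 23 (25 mM replicate 2), 22 (5 mM replicate 1), 44 (5 mM replicate 3) and 758 (25 mM replicate 3). With only the 6 libraries and all genes limma called 0, with 1827 at an unadjusted p under 0.05, and the share of called genes that were higher, 67.5%, became 84.6% in the 6-library fit above a mean of 20, 77.8% with pseudocount 10 and 44.7% with array weights. The difference between the states was itself called for 3127 genes, 1686 higher and 1441 lower, 390 at least 2-fold, and for 2916 with only the 12 libraries of the line and a mean of at least 20.

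Gene lists were tested for the same difference in 501mel. The ATF4 list had 15 of 21 members, 18 over the list alone, with a lower response in suspension and 0 with a higher one, led by TRIB3 at −0.9 ± 0.08 and SESN2 at −1.6 ± 0.15 (SE; adjusted p = 3.2e-16, and 0.053 with an estimated correlation). Of 20 S phase genes 15 had a higher one, 17 over the list alone, with PCNA at 0.65 ± 0.06 and CDC6 at 0.86 ± 0.08 (adjusted p = 5.5e-15, and 0.053 with an estimated correlation). SRF targets went down in 11 of 21 and up in 1 (2 over the list alone), with ZYX at −0.64 ± 0.07 (adjusted p = 4.7e-05, and 0.053 with an estimated correlation). Immediate early genes went down in 9 of 16 (11 over the list alone) and up in 1, with EGR1 at −0.96 ± 0.12 (adjusted p = 5.1e-06, and 0.2 with an estimated correlation).

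The glucose comparison was repeated in WM266-4. TXNIP fell in attached cells from 1415 ± 24 to 97.25 ± 6.84 counts (SD, n = 3), a log2 change of −3.85 ± 0.06 (adjusted p = 1.9e-23), and in suspension from 4464 ± 82.2 to 3048 ± 93.8, a change of −0.55 ± 0.06 (adjusted p = 0.00012). ARRDC4 fell in attached cells from 584 ± 46.8 to 191.5 ± 16.9 (−1.6 ± 0.13, adjusted p = 5.9e-08) and stood at 2051 ± 115 and 1601 ± 80.1 in suspension (−0.36 ± 0.13, adjusted p = 0.095). The difference between the states was 3.3 ± 0.09 for TXNIP (adjusted p = 2.5e-18) and 1.25 ± 0.18 for ARRDC4 (adjusted p = 0.0014). In each attached comparison 3 of 3 libraries at 5 mM lay below those at 25 mM. The other 5 MondoA and ChREBP targets were not called over all genes in attached cells, and the list had 0 higher and 2 lower, 1 and 3 over the list alone (adjusted p = 3.1e-07, and 0.0022 with an estimated correlation).

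**Figure D4:**
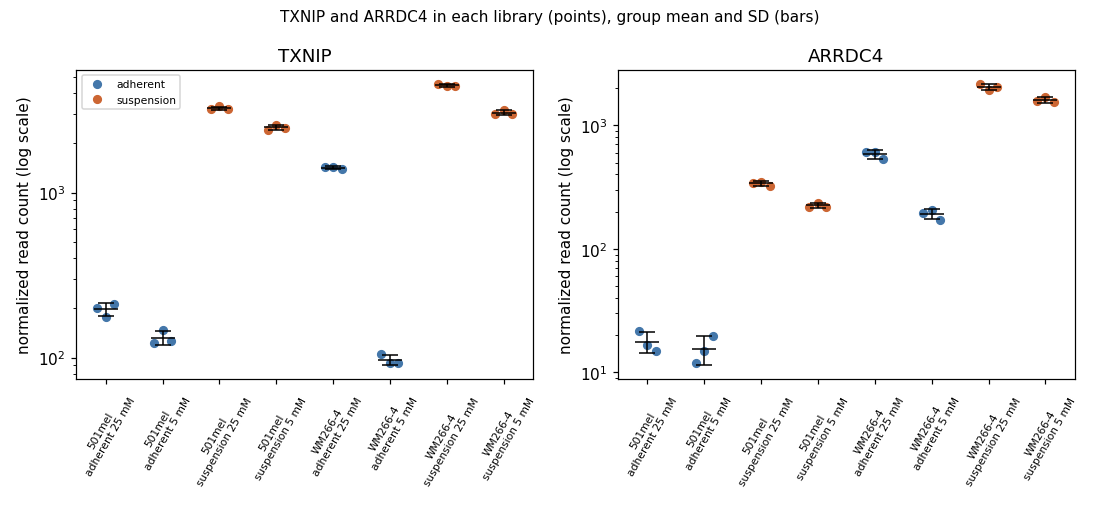
Normalised read counts of TXNIP and ARRDC4 in each library (points) with group means (lines), on a log axis, for the 8 groups. TXNIP in attached WM266-4 lies at a mean of 1415 at 25 mM and 97.25 at 5 mM, and at a mean of 2477 or more in every suspension group.

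Hypoxia-response genes also fell in attached WM266-4 at 5 mM glucose. Of 18 measured members 5 fell, 8 adjusted over the list alone, and 0 rose, with VEGFA at −0.41 ± 0.08 (SE), BNIP3 at −0.36 ± 0.07 and DDIT4 at −0.42 ± 0.08 (adjusted p = 5.8e-11, and 0.0022 with an estimated correlation). SRF targets had 2 of 21 higher, 6 over the list alone, with ACTG1, a cytoplasmic actin gene, at 0.21 ± 0.04 (adjusted p = 1.5e-06, and 0.022 with an estimated correlation). SLC2A1 and PDK1 of the glycolysis list were 1.31-fold and 1.3-fold lower, with 2 of 22 members lower, 6 over the list alone (adjusted p = 1.4e-08, and 0.12 with an estimated correlation). S phase genes had 2 of 20 lower, and 14 lower and 1 higher over the list alone, with CDC6 1.25-fold lower (adjusted p = 1.4e-11, and 0.072 with an estimated correlation). Cholesterol synthesis had 1 of 24 higher, 8 over the list alone, FDPS by 1.17-fold (adjusted p = 5.1e-11, and 0.072 with an estimated correlation). C2orf72 and RAB20 were 1.7-fold and 1.64-fold lower. The limma fit called 95 genes, 40 higher and 55 lower, 12 at least 2-fold. That count was 1579 with only these 6 libraries and a mean of at least 20 (chosen after seeing the data), 395 with the 6 libraries and all genes, 704 with array weights, 126 with edgeR and 211 with DESeq2. Without 1 adherent library it was 26 (25 mM replicate 1), 51 (25 mM replicate 2 or 3), 30 (5 mM replicate 2) and 28 (5 mM replicate 3). The share higher, 42.1%, became 29.2% under equal totals and 28.6% with edgeR.

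The last glucose comparison was that of suspended WM266-4. EFNB2, an ephrin ligand gene, rose 2.53-fold (adjusted p = 0.0023), SULT1C2 1.96-fold (adjusted p = 0.0027) and CCN2 1.7-fold (adjusted p = 0.0014), each with 3 of 3 libraries on one side. Other genes called higher were AFF3, FAM107B, DCDC2C, SNTG2, LIMCH1, SLAMF7 and IL36RN, by log2 changes of 0.82 to 1.1, and called lower PPFIA4, DNPH1, EFNB3, B4GALNT4 and PACSIN3, by −0.59 to −0.7. The calls of AFF3, DCDC2C, SNTG2, SLAMF7, IL36RN and B4GALNT4 ended without suspension 25 mM replicate 2 (adjusted p between 0.082 and 0.2) and without 5 mM replicate 2 (between 0.064 and 0.28). All of these but AFF3 also ended without 25 mM replicate 3, all but B4GALNT4 without 5 mM replicate 3, B4GALNT4 without 5 mM replicate 1, and IL36RN without 25 mM replicate 1. Of 21 ATF4 genes 6 rose, 12 over the list alone (median 0.22, adjusted p = 3.6e-06, and 0.27 with an estimated correlation). Of 24 cholesterol genes 7 fell, 12 over the list alone, with ACAT2 at −0.4 ± 0.06 (adjusted p = 4e-05, and 0.27 with an estimated correlation). Of 22 YAP targets 5 rose, 8 over the list alone (adjusted p = 4.3e-05, and 0.27 with an estimated correlation). The limma fit called 1221 genes, 480 higher and 741 lower, 48 at least 2-fold, and edgeR 1422 and DESeq2 1516. With only these 6 libraries the count was 13 above a mean of 20 (chosen after seeing the data) and 1 over all genes, with 3148 at an unadjusted p under 0.05. Of EFNB2, SULT1C2 and CCN2 only SULT1C2 was still called in the fit above a mean of 20. It was 382 without suspension 25 mM replicate 2, 648 without 25 mM replicate 3 and 461 without 5 mM replicate 2. The counts of 95 and 1221 therefore cannot be read as a difference between the states, since their order turned in the fits of only the compared libraries. The tested difference between the states was called for 302 genes, 125 higher and 177 lower, 21 at least 2-fold, and for 588 with the 12 libraries of the line and a mean of at least 20. The count was 691 without suspension 5 mM replicate 1 and 547 without suspension 25 mM replicate 1. It was between 69 and 170 without any adherent library, without suspension 25 mM replicate 2 or 3, or without suspension 5 mM replicate 2.

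The lines were last compared with each other, attached at 25 mM glucose, as WM266-4 against 501mel. Matrix genes stood far higher in WM266-4. COL1A2 (ENSG00000164692), a chain of type I collagen, had 29410 ± 834 counts there and 4.063 ± 2.88 in 501mel (SD, n = 3), and COL4A1 22100 ± 702 and 7.16 ± 6.73. All 22 measured extracellular matrix genes were higher, FN1, fibronectin, by 31-fold (median 5.13, adjusted p = 5.1e-10, and 0.0036 with an estimated correlation). IGFBP3 had 42040 ± 739 counts against 4.07 ± 3.04, the neural cadherin gene CDH2 7503 ± 103 against 1.867 ± 1.87, L1CAM 9853 ± 175 against 2.19 ± 1.96 and IGFBP5 14810 ± 449 against 2.497 ± 0.552. The integrin gene ITGA4 had 6205 ± 240 against libraries listed at 0, HLA-DRA 4641 ± 105 against 0.31 ± 0.537, and FAM20C 6308 ± 58.3 against 0.6267 ± 1.09. In 501mel the receptor kinase gene KIT (ENSG00000157404) had 8366 ± 175 counts against 1.64 ± 0.58, APCDD1 11900 ± 396 against 0.6567, PDK4, a pyruvate dehydrogenase kinase gene, 5906 ± 52.7 against 0.6533, and CPXM1 16920 ± 399 against 13.76 ± 4.4. SLCO5A1, ASB4, ARHGAP29, BAAT, KRTAP19-1 and CTLA4 likewise had between 950.3 and 5675 counts in 501mel and at most 2.297 in WM266-4. Of 18 invasive melanoma genes 14 were higher and 2 lower, SERPINE2 by 25.9-fold and PLAUR by 12.8-fold (adjusted p = 0.00037, and 0.031 with an estimated correlation). Of 15 p53 targets 14 were higher, PHLDA3 by 19.4-fold (adjusted p = 3.4e-05, and 0.0036 with an estimated correlation). Of 18 hypoxia-response genes 17 were higher, P4HA2 by 10.6-fold (adjusted p = 6.1e-05, and 0.043 with an estimated correlation). The peroxisomal list had 13 of 18 members higher and 3 lower, with CRAT 6.43-fold and EHHADH 3.87-fold higher and the transporter gene ABCD3 3.11-fold lower (adjusted p = 0.011, and 0.2 with an estimated correlation). CROT was 3.18-fold higher (adjusted p = 5.8e-17).

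Other lists differed between the attached lines too. Of 19 integrin and focal adhesion genes 17 were higher in WM266-4, ITGB5 by 18.4-fold (adjusted p = 5.1e-06, and 0.17 with an estimated correlation). Of 16 interferon-stimulated genes 13 were higher, HLA-B by 26.1-fold (adjusted p = 0.0036, and 0.21 with an estimated correlation), as were 16 of 22 glycolysis genes, PDK1 by 4.42-fold (adjusted p = 0.0033, and 0.44 with an estimated correlation). Lower were 19 of 21 G2 and M phase genes, CDK1 by 2.05-fold (adjusted p = 3.4e-05, and 0.44 with an estimated correlation), and 17 of 20 S phase genes, MCM2 by 4.65-fold (adjusted p = 0.00018, and 0.43 with an estimated correlation). Also lower were 15 of 21 ATF4 genes, PHGDH by 4.43-fold (adjusted p = 0.0049, and 0.5 with an estimated correlation), and 14 of 18 ribosome biogenesis genes (15 over the list alone), NOP56 by 3.33-fold (adjusted p = 0.00018, and 0.2 with an estimated correlation). Of 18 MITF targets 6 were higher and 11 lower (median −0.91, adjusted p = 0.053). The limma fit called 14029 genes, 7455 higher and 6574 lower in WM266-4, 7342 of them at least 2-fold. Quantile normalization moved the median of all genes by −0.405 and the share higher from 53.1% to 42.8%, and scaling to equal totals moved the median by −0.138.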

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

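The values given first here are differences of effects tested by an interaction in limma, which were planned, whereas 7 of the tests of explanations further on were chosen after the result was seen. Suspension acted differently in the lines for 10837 genes. CROT and CRAT responded less in WM266-4, by −0.79 and −1.5 on the log2 scale. The largest differences toward WM266-4 were GGT4P at 7.2, CCN1 at 7.06, MAGEB2 at 5.91, CYP4F3 at 5.68 and CXCL8 at 5.49, and toward 501mel DLK1 at −6.35, FBXO43 at −5.62, TCHH at −5, RNASE1 at −4.93 and ANXA3 at −4.7. edgeR did not call CYP4F3, and DLK1 had 1 to 4 reads in each group of WM266-4. Among lists, the median difference was −0.5 for peroxisomal fatty acid oxidation, −0.54 for mitochondrial fatty acid oxidation, −0.68 for cholesterol synthesis, −1.55 for S phase and −2.37 for G2 and M phase genes. It was 0.61 for mitochondrially encoded mRNAs, 1.43 for ATF4 genes, 0.53 for NRF2 targets, 0.53 for ribosome biogenesis, 0.07 for ribosomal proteins, 0.49 for YAP targets, 1.81 for immediate early genes and 2.04 for NF-kappaB genes. None of these list calls holds with an estimated correlation.

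In 501mel the suspension response differed by glucose for 3127 genes, and CRAT by 0.43. TAFA4 at 2.43, PTPRN2 at 2.13, RP1 at 2, SNTG2 at 1.95 and AMOTL2 at 1.63 were the largest upward, and HMOX1 at −2.51, DDIT4 at −1.88, FOS at −1.72, BCAN-AS1 at −1.71 and CHAC1 at −1.65 downward. BCAN-AS1 is antisense and the strand setting is not given in the sources used here, so its reads were not separated from those of the opposite strand. HMOX1 in adherent cells at 5 mM had 9358 ± 5710 counts, a wide spread over n = 3. With only the libraries of the line the calls of BCAN-AS1, FOS and RP1 ended. List medians were −0.03 for oxidative phosphorylation, −0.53 for ATF4 genes, 0.2 for the unfolded protein response, 0.42 for S phase genes, −0.06 for ribosomal proteins, −0.18 for MITF targets, −0.24 for SRF targets, 0.2 for extracellular matrix and −0.47 for immediate early genes. With an estimated correlation none of these list calls held.

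In WM266-4 the suspension response differed by glucose for 302 genes. These include TXNIP at 3.3, AFF3 at 1.91, ACTL8 at 1.82, FAM107B at 1.74 and ARRDC4 at 1.25, and downward TRPM1 at −0.84, GALNT3 at −0.76, HSF4 at −0.74, MATCAP1 at −0.71 and GJB1 at −0.7. The calls of AFF3, HSF4 and GALNT3 each ended without 1 of several libraries, among them suspension 25 mM replicate 2, and edgeR did not call ACTL8 or FAM107B. With only the libraries of the line the calls of GJB1, TRPM1, HSF4 and GALNT3 ended. List medians were −0.09 for mitochondrial fatty acid oxidation, −0.15 for fatty acid synthesis, −0.24 for cholesterol synthesis, 0.09 for hypoxia-response genes, 0.41 for MondoA targets, −0.14 for oxidative phosphorylation, −0.11 for the tricarboxylic acid cycle and −0.15 for mitochondrially encoded mRNAs. They were 0.22 for ATF4 genes, 0.11 for NRF2 targets, 0.14 for G2 and M phase genes, −0.09 for ribosomal proteins, −0.13 for MITF targets, 0.15 for the invasive list, 0.23 for YAP targets and −0.09 for SRF targets. None of the list calls for this difference by glucose holds with an estimated correlation.

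Each comparison of 3 with 3 libraries was repeated over the 10 ways of dividing its 6 libraries, a test written down before its result was seen. For each of the 4 suspension comparisons 1 of the 10 divisions, the real one, called as many genes, and the highest other count was 15 and 2 in 501mel at 25 and 5 mM and 3 and 2 in WM266-4. Adherent 501mel at 5 mM had 1 of 10, with 49 as the highest other, adherent WM266-4 1 with 3, suspended WM266-4 1 with 63, and the attached lines 1 with 0. With 10 divisions the splits are too few to give a small p. In suspended 501mel at 5 mM 2 of the 10 called as many, and the highest other count was 916 beside the real 77, which points to a structure of the samples. That division set 25 mM replicate 3 and 5 mM replicates 1 and 3 against the other libraries. These 3 had 4.95% to 5.09% of reads in mitochondrial genes against 3.65% to 4.26%, 1.21% to 1.33% in lincRNA and antisense genes against 1.08% to 1.16%, and 23186 to 23767 genes with a read against 22531 to 22912. These features were looked up after the result was seen, no label explains them, and the real division itself called 758 without 25 mM replicate 3. For the differences of responses 100 divisions were counted, the real one included. Between the lines 1 of them, the real one, called as many (highest other 8928, real 10837). In 501mel 4 did, the real one included (highest other 3715, real 3127), and in WM266-4 2 (highest other 616, real 302). These divisions exchanged libraries between groups, which also broke up the responses themselves. The counts therefore cannot test the difference of responses alone.

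The response of 501mel to 5 mM glucose was called in many genes in adherent cells and in few in suspension. Unequal spread between libraries may have hidden a response in suspension, but after subtracting the replicate variance the SD of the log2 fold changes was 0.254 in adherent and 0.0823 in suspended cells over 10779 genes. That ratio of 3.09 was 1.87 at the lowest without 1 library, so the adherent SD stayed the larger one. The ratio is not stable, since without another library no suspension variance was left after the subtraction and the ratio had no finite value. It rests on the replicate variance of these same libraries, so it cannot exclude that a response in suspension was hidden. One library could decide the pattern. The count of genes with a called difference between the states, 3127, was 2549 at the lowest without 1 library. That argued against it for the difference between the states only. The count in suspension, 77, was 15 to 758 without 1 library, so 1 library can decide how few genes were called there. An unlabelled batch of culture or library preparation cannot be told apart from glucose, since the number of labels that give a batch is 0.

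The genes called at 5 mM glucose in suspended WM266-4 may reflect that the libraries differ in the extent of the suspension response. Across genes, which are not independent replicates, the leading deviation among these libraries correlated with the mean suspension effect at 0.335 in absolute value. That was just over a limit of 0.3, which was set after the pattern was seen. The 5 mM effect in suspension itself correlated with the mean suspension effect at 0.444. Of 1162 called genes with a mean of at least 100, 969 moved as in suspension. The extent of the response, measured along the mean effect of these same libraries, was 0.97, 0.901 and 0.975 at 25 mM and 0.997, 1.09 and 1.07 at 5 mM (n = 3). The difference in extent goes with glucose, and with 3 libraries in each group a stronger response caused by glucose stays open. The spread pooled over all groups may also be too small for these libraries, and the count of 13 with only the 6 libraries goes with that. In the same fit over all genes 3148 had an unadjusted p under 0.05, so the fewer libraries may also have lowered the count.

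TXNIP fell at 5 mM glucose far more in adherent WM266-4 than in suspension. One library could decide this, but the lowest difference without 1 library was 3.27. Scaling could also matter, but the lowest difference under another scaling or tool was 3.3, and both values argued against these explanations. The MondoA and ChREBP target list as a whole might have lost its glucose response in suspension, and 2 of its 7 members were called higher in the difference. The other 5 had no called change in attached cells to lose, so this count cannot exclude a change of the list, whose median difference was 0.41, and that explanation stays open.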

How the results depend on the processing

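The settings were chosen before the result was seen, except the mean of at least 20 and the lists under other scalings, which were chosen after it was seen. Of the counts of genes 233 stayed and 59 moved more than 1.5-fold. CROT and CRAT stayed in 527 results, were stronger in 6 and weaker in 3, gene lists stayed in 605 and were weaker in 214, and named genes stayed in 3628 and were weaker in 141. For genes and lists, stayed means that the call at an adjusted p under 0.05 was unchanged. Weaker means that the call was lost and stronger that it was gained, and the size of the effect was not compared. The overlaps moved in 4 of 4 results, and the number of list calls stayed in 4 and moved in 1. The direction of 1 called list reversed, that of the cytosolic ribosomal proteins in the difference between the lines under quantile normalization (adjusted p = 0.93, with a range of 7.6e-05 to 0.93 over its alternatives). The majority of called genes changed side by more than 10 points between the lines, from 53.1% to 42.8% higher under quantile normalization, and in suspended 501mel at 5 mM glucose, from 67.5% to 44.7% with array weights and 43.6% with the replicate block. In other comparisons shares near 50% crossed it by smaller moves. The cause of the moves was not tested, apart from those that follow from a stricter threshold.

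With at least a 2-fold change the counts were 2500 and 3069 for suspension in 501mel at 25 and 5 mM, 3046 and 3401 in WM266-4, 457 and 19 for 5 mM glucose in adherent and suspended 501mel, 12 and 48 in WM266-4, 7342 between the lines, and 3220, 390 and 21 for the differences between lines, in 501mel and in WM266-4. Shared genes were then 883 and 1074 between the lines at 25 and 5 mM, and 1828 and 2525 within 501mel and WM266-4. With an adjusted p under 0.01 the glucose counts were 9 in suspended 501mel, 23 and 387 in adherent and suspended WM266-4, and the differences by glucose 1691 in 501mel and 32 in WM266-4.

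For 5 mM glucose in suspended 501mel the count was 126 with pseudocount 10, 0 with only the compared libraries, 26 with these and a mean of at least 20, 1656 with array weights, 189 with DESeq2 and 234 with a replicate block. Whether the replicate numbers pair the libraries stays open. Of 36 pairs of the same number 9 correlated above 0.1, with a range of −0.176 to 0.314, and 0.059, 0.231 and 0.314 between the glucose concentrations in suspended 501mel. Of 24 libraries 11 correlated best with their own number, for which no chance value was computed, so the block is given only here. In adherent WM266-4 the count was 395 with only the compared libraries, 1579 with these and a mean of at least 20, 704 with array weights and 211 with DESeq2. In suspended WM266-4 it was 1 and 13 with the compared libraries, without and with the mean of at least 20. The difference by glucose in WM266-4 was 151 with no filter, 463 with quantile normalization, 1197 with array weights, 648 with DESeq2, 546 with the block and 588 with its own libraries and a mean of at least 20.

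CRAT in WM266-4 at 25 mM was 0.21 with quantile normalization (adjusted p = 0.0039), 0.17 with equal totals (adjusted p = 0.021), and 0.12 with only the compared libraries, both without and with a mean of at least 20 (adjusted p = 0.034 and 0.022), while over all its alternatives the adjusted p lay between 0.0039 and 0.22. The fall of CROT at 5 mM glucose in adherent 501mel was −0.25 with only the compared libraries, both without and with a mean of at least 20 (adjusted p = 0.16 and 0.068), and lay between −0.33 and −0.14 without 1 library, where it lost the call without replicate 3 at 5 mM (adjusted p = 0.12). Over all its alternatives the adjusted p lay between 0.00076 and 0.16. The difference by glucose of CROT in 501mel was 0.26 with array weights (adjusted p = 0.038) and lay between 0.12 and 0.31 without 1 library, with an adjusted p of 0.02 to 0.4 over all its alternatives. List calls numbered 14 with an estimated correlation, beside 164. Without 1 library the glucose count was 15 to 758 in suspended 501mel, 26 to 80 in adherent WM266-4 and 382 to 1582 in suspended WM266-4, and the difference in WM266-4 69 to 691.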

Other observations

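Some lists showed no call in any suspension comparison. Of 22 extracellular matrix genes 9 rose and 7 fell in suspended 501mel at 25 mM (median 0.15, adjusted p = 0.93), and the median turned to −0.03 under quantile normalization. In WM266-4 5 rose and 11 fell (median −0.31, adjusted p = 0.2). Of 19 integrin and focal adhesion genes 7 rose and 6 fell in 501mel and 5 rose and 11 fell in WM266-4 at 25 mM (adjusted p = 0.93 and 0.087). Of 11 epithelial-mesenchymal transition genes 4 rose and 5 fell in 501mel at 25 mM, with a median of −0.28, a mean of 0.08 and adjusted p = 0.69, and in WM266-4 5 rose and 1 fell (adjusted p = 0.36). The TGF-beta list had 4 higher and 4 lower of 14 in 501mel at 25 mM (adjusted p = 0.93), lipid uptake and PPAR targets 8 and 7 of 19 (adjusted p = 0.93), lysosome genes 8 and 6 of 17 (adjusted p = 0.54), hypoxia-response genes 6 and 8 of 18 (adjusted p = 0.93) and interferon-stimulated genes 7 and 3 of 16 (adjusted p = 0.11). The histone list had 0 higher and 1 lower of 9, and markers of other cell types 2 and 2 of 8 (both adjusted p = 0.93). An adjusted p that misses the threshold does not show that a list did not change.

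The next questions were chosen after the result was seen. TXNIP and ARRDC4 rose in suspension in both lines, and in WM266-4 TXNIP fell at 5 mM glucose far more where cells were attached. In 501mel TXNIP changed by −0.57 in attached and −0.39 in suspended cells, and the difference of 0.18 was not called (adjusted p = 0.18). A candidate explanation, for WM266-4 alone, is that attachment sets how far TXNIP follows glucose, and the difference of at least 3.27 without any 1 library leaves it open. Measuring TXNIP protein and glucose uptake over a series of glucose concentrations in attached and suspended WM266-4 could test it.

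Cholesterol genes fell in suspension in both lines while CROT rose in both and CRAT in 501mel. Whether sterol synthesis falls because lipids are taken up from serum or released from stores cannot be seen in RNA. The fall could be tested with labelled acetate in attached and suspended cells, with and without serum lipids. Of the 14 list calls that hold with an estimated correlation, 4 are cholesterol synthesis, 1 in each suspension comparison.

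The glucose response of suspended cells needs more libraries with a recorded culture. The count of 13 with only the 6 libraries in WM266-4 and of 26 in 501mel, both with a mean of at least 20, leave the size of that response open, and it may be smaller or larger than the counts of 1221 and 77.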
